A study of Escherichia coli with 90 samples.

How the data were processed

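Each of the 30 groups of 3 libraries (16 of DH10B-GFP, 14 of MG1655-GFP) was a strain, a construct, empty plasmid or no plasmid, and a time after induction. Per the labels' protocols, cells grew at 37 °C in plate-reader wells, 4 wells were pooled per time point, ribosomal RNA was depleted, and libraries were made with random hexamers and a Nextera XT kit with 13 PCR cycles, which keeps no strand. The replicate letters of the titles give replicates 1 to 3. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.1 and mapped with BWA 0.7.12. The notes name the builds ASM584v2 and mm8, the latter a mouse build, without their role, and no counting tool. The deposited values are counts, read as whole-number reads per gene row because totals differed between libraries, with no normalization seen.

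The tables of DH10B held 4320 rows with 4200 names and those of MG1655 4497 rows with 4451. Rows repeating a name were summed (120 extra rows in DH10B, 46 in MG1655). Names were matched to a reference list of genes: 3583 and 4237 directly, 498 and 195 by synonym, and 119 and 19 not. Rows of ribosomal and transfer RNA were left out of the tests. Genes without a row in the DH10B tables, among them lacZ, araA, araB, araC, araD, recA and fliC, are not analysed here in that strain, nor are reads of the constructs, which have no rows of their own (the lacZ row of MG1655 does not part genomic from construct reads).

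Each strain was fitted with 1 edgeR 4.0.16 model of group means in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood F tests), and the strain differences with 1 model of both strains over 3081 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 32 comparisons were each construct with its empty plasmid (16), the average of the 4 constructs at 60 min (2), its difference between 60 and 15 min (2), the difference of each construct effect between strains at 60 min (4), empty plasmids with no plasmid (6, DH10B) and 60 with 15 min in empty plasmids (2). The gene lists, written from general knowledge of E. coli, were tested with camera of limma 3.58.1 at the preset correlation of 0.01, p adjusted over lists, and again with an estimated correlation and with fry. They cover heat shock (RpoH), envelope stress (RpoE, and Cpx), phage shock, ribosomal proteins, translation factors, ribosome hibernation, RNA polymerase and sigma factors, general stress (RpoS), acid resistance, SOS response, oxidative stress, cold shock, amino acid biosynthesis, purine and pyrimidine synthesis, glycolysis and PTS, TCA cycle, ATP synthase, aerobic respiration, anaerobic metabolism, flagella and chemotaxis, iron uptake (Fur), alternative sugar uptake, toxin-antitoxin, arabinose, rhamnose and lac genes. Some lists share genes.

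Genes were named by a rule: 12 heat shock sentinels and the construct and inducer genes whatever their values; the 5 highest and 5 lowest fold changes among called genes with mean CPM of at least 10 and no overlap between groups (3 and 3 for constructs at 15 min); for the average the 10 highest and 10 lowest with 1 sign in all 4 constructs; and up to 4 list members with the smallest p. Other genes, such as gltA, malE, rpsH or katE, were chosen as list members or after their values were seen. Where a group had no read over its 3 libraries, folds are lower bounds with 3 reads in the group, and with 1 to 3 reads they are ratios with a 95% counting interval.

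Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, all gene rows kept, the replicate number as a block, a fit of only the groups compared, and leaving out each library (or replicate number, for comparisons of many groups); the lone pair left in a group is assumed to vary as the other groups do. Leaving out the 3 shallow libraries (under 1000000 reads) was post hoc. Residuals of construct and plasmid correlated above 0.1 in 40 of 48 same-replicate pairs (median 0.234, all 3 in 10 of 16 comparisons). 44 correlated best with their own number, and 38 of 45 between times. The main model is unpaired. No replicate pair of 90 was identical (chi-square per gene 2.48 to 80.9). The model was tested on simulated data, with 200 genes changed by 1.5, 2 and 4-fold: of those passing the filter it recovered 6.50%, 41.9% and 80.0% for M1 in DH10B at 60 min (62, 62 and 65 genes), 13.8%, 56.1% and 81.8% in MG1655 (65, 66 and 66) and 3.00%, 17.2% and 55.6% (66, 64 and 63) for the M1 strain difference, and 7.90%, 2.90% and 2.00% of the calls were unchanged genes.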

Results

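RNA was sequenced from Escherichia coli DH10B-GFP and MG1655-GFP, strains with a GFP cassette in the genome, carrying 1 of 4 synthetic constructs (H3, Lux, M1 or LacZ) or an empty plasmid, 15 and 60 min after the inducer was added. H3 and Lux were compared with empty pSB1C3 and M1 with empty pLys, all in arabinose, and LacZ with empty pD864 in rhamnose. DH10B also had libraries with no plasmid. This gave 90 libraries in 30 groups of 3, 48 of DH10B and 42 of MG1655. Comparing a construct with its empty plasmid asks which host genes respond first to the burden of expressing it. Total counts per library ran from 129883 to 4842354 (median 2611985), of which ribosomal RNA took 41.0% to 91.5%, so that 76529 to 1173164 reads (median 572967) fell on other genes. The bound used for a count of 0, 3 reads in a library, stood for 2.56 to 39.2 counts per 1000000 (CPM). In DH10B, 3 libraries held under 1000000 reads: no plasmid at 60 min replicate 2 (129883), pSB1C3 at 15 min replicate 1 (294256) and pD864 at 15 min replicate 3 (453669). The labels do not say that replicates came from separate cultures, so each p measures a difference against the spread between these samples. Values are means ± SD in CPM over 3 libraries and log2 fold changes (log2FC) ± SE, with p from edgeR's quasi-likelihood test adjusted over 2979 genes in DH10B and 3011 in MG1655. Counting intervals and at-least folds cover counting error only. Set-test calls given without a second p also held with an estimated correlation.

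A group of 12 sentinel genes of the heat shock response, chosen before the data were examined (htpG, ibpA, ibpB, dnaK, dnaJ, grpE, groL, groS, clpB, lon, hslU and fxsA), is followed through every comparison of a construct with its plasmid. They encode chaperones, proteases and other proteins made when proteins misfold, are transcribed with the sigma factor RpoH, and belong to a list of 20 heat shock genes. With each count of called genes stands the percentage of genes whose 3 values all lie above or all below the other 3, where chance gives 10%. For a gene list, members called precede those called with p adjusted over the list alone (list alone). Next comes camera's false discovery rate (FDR), its p adjusted over all lists.

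In DH10B the arabinose transport genes were far higher with H3, Lux or M1 than with the empty plasmid in the same inducer. At 15 min araE rose from 13.98 ± 9.34 to 3066 ± 505 CPM (log2FC 7.70 ± 0.40, adjusted p = 6.81e-22) with H3, to 3213 ± 762 CPM (log2FC 7.76 ± 0.40, adjusted p = 2.45e-22) with Lux and from 22.4 ± 8.02 to 2858 ± 547 CPM (log2FC 6.93 ± 0.36, adjusted p = 3.90e-22) with M1. At 60 min it rose from 19.2 ± 7.29 to 7508 ± 1126 CPM (log2FC 8.62 ± 0.38, adjusted p = 3.59e-25) with H3, to 6342 ± 1069 CPM (log2FC 8.38 ± 0.38, adjusted p = 3.77e-25) with Lux and from 14.7 ± 8.17 to 381 ± 25.1 CPM (log2FC 4.87 ± 0.38, adjusted p = 1.67e-15) with M1. The binding-protein gene araF reached 3747 ± 361 CPM with H3 (log2FC 7.79 ± 0.35, adjusted p = 3.59e-25) and 63.5 ± 27.6 CPM with M1 (log2FC 1.90 ± 0.38, adjusted p = 5.39e-05) at 60 min, and araG, araH and araJ had log2FC of 6.23 to 7.20 with H3. All 5 arabinose genes measured in DH10B were called higher in each of these 6 comparisons (list alone 5, camera FDR = 0.00249 for M1 at 60 min and at most 6.75e-32 in the others). araE was also higher with LacZ at 60 min (36.5 ± 9.91 against 14.4 ± 6.01 CPM, log2FC 1.42 ± 0.39, adjusted p = 0.00771), a call lost without pD864 replicate 1 (adjusted p = 0.0602).

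In MG1655, which has its own ara operon, most arabinose genes were lower with M1, and with H3 and Lux at 15 min. With M1 at 60 min araA fell from 2035 ± 137 to 92.6 ± 12.2 CPM (log2FC -4.45 ± 0.23, adjusted p = 7.18e-20), and araB, araD, araE and araF had log2FC of -3.54 to -4.83, while the regulator gene araC rose from 47.4 ± 20.8 to 696 ± 222 CPM (log2FC 3.83 ± 0.43, adjusted p = 8.70e-09). The count lower was 8 of 9, list alone 8, camera FDR = 1.48e-12. At 15 min araE fell from 2015 ± 210.4 to 135 ± 10.2 CPM (log2FC -3.90 ± 0.30, adjusted p = 3.61e-12) with Lux, to 289 ± 121 CPM (log2FC -2.82 ± 0.28, adjusted p = 1.03e-09) with H3 and from 1095 to 470.1 CPM (log2FC -1.23 ± 0.27, adjusted p = 0.000770) with M1. The counts lower were 7 of 9, list alone 7, camera FDR = 4.18e-47 with Lux (araA, araB, araD and araF -2.07 to -2.99), 7 of 9, list alone 7, camera FDR = 1.11e-05 with H3 (the same genes -0.78 to -1.07) and 6 of 9, list alone 7, camera FDR = 8.14e-05 with M1 (araA, araB and araD -1.11 to -1.23). At 60 min with Lux araE fell from 1088 to 305 CPM (log2FC -1.83 ± 0.27, adjusted p = 1.13e-05) and araA, araB and araD had -0.74 to -0.89 (4 of 9, list alone 4, camera FDR = 0.00239). With H3 at 60 min araC rose from 47.1 ± 15.4 to 199 ± 31.0 CPM (log2FC 2.04 ± 0.43, adjusted p = 0.00314), and 3 of 9 arabinose genes were called higher (camera FDR = 0.0954). With H3 at 15 min calls were lost for araA and araD without H3 replicate 1 or 3 or pSB1C3 replicate 2 or 3 (adjusted p 0.0562 to 0.162). araF was lost without H3 replicate 1 or 3 or pSB1C3 replicate 1 (adjusted p 0.0821 to 0.0919). With Lux at 60 min they were lost for araB without Lux replicate 2 (adjusted p = 0.0896). araD was lost without any 1 Lux library or pSB1C3 replicate 2 or 3 (adjusted p 0.0636 to 0.145).

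With LacZ in MG1655 lacZ rose from 13.8 ± 6.55 to 15204 ± 2520.4 CPM (log2FC 10.09 ± 0.36, adjusted p = 5.34e-25) at 15 min and from 14.3 ± 3.78 to 86631 ± 6877 CPM (log2FC 12.52 ± 0.38, adjusted p = 1.77e-27) at 60 min. The neighbouring lac genes were higher in both strains: at 60 min lacY rose from 4.66 ± 3.61 to 152 ± 26.3 CPM (log2FC 4.94 ± 0.45, adjusted p = 1.55e-12) in DH10B and from 2.19 ± 1.91 to 302.9 ± 63.6 CPM (log2FC 6.93 ± 0.58, adjusted p = 1.02e-11) in MG1655, and lacA had log2FC of 3.93 ± 0.42 and 6.40 ± 0.52 (lac list 2 of 3, list alone 2, camera FDR = 9.97e-08 in DH10B, 3 of 4, list alone 3, camera FDR = 2.43e-85 in MG1655). At 15 min lacY in DH10B and lacA in MG1655 had log2FC of 5.24 ± 0.45 and 8.15 ± 0.54, and the ratios were 239 (95% counting interval 81.3 to 1161) for lacA in DH10B and 1438 (95% counting interval 258 to 56839.9) for lacY in MG1655. Genes for rhamnose uptake and breakdown were lower with LacZ than with empty pD864. At 60 min rhaA fell from 3245 ± 540.4 to 331 ± 38.7 CPM (log2FC -3.29 ± 0.37, adjusted p = 4.31e-08) in DH10B (6 of 7, list alone 6, camera FDR = 1.88e-16) and from 1627 ± 281 to 75.4 ± 15.0 CPM (log2FC -4.44 ± 0.34, adjusted p = 8.40e-13) in MG1655 (6 of 7, list alone 7, camera FDR = 3.52e-56). rhaB, rhaD and rhaT had log2FC of -1.60 to -3.32 in DH10B and, with rhaM and rhaR, -3.39 to -4.33 in MG1655. At 15 min rhaA, rhaB, rhaD, rhaT and rhaM had -2.68 to -4.16 in DH10B, and the first 4 of these -2.84 to -3.43 in MG1655. Calls lost in DH10B were rhaB and rhaM by DESeq2 (adjusted p 0.221 to 0.474) at 15 min and rhaB by DESeq2 (adjusted p = 0.176) at 60 min. lacY was lower in DH10B at 60 min with H3, Lux and M1 (log2FC -1.91 ± 0.39, -1.89 ± 0.38 and -2.64 ± 0.56), as was lacA with H3 and Lux (-1.53 ± 0.38 and -1.97 ± 0.39) and, by a ratio of 15.6 (95% counting interval 5.17 to 77.3), with M1. With H3 the call was lost for lacA without H3 replicate 1 or 3 or pSB1C3 replicate 2 (adjusted p 0.0582 to 0.0820). In MG1655 lacZ was lower with M1 at 60 min (log2FC -2.36 ± 0.64, adjusted p = 0.00241).

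With H3 in DH10B heat shock genes were higher at both times. At 15 min dnaK, the main Hsp70 chaperone gene, rose from 847 ± 171 to 10809.6 ± 1383 CPM (log2FC 3.69 ± 0.23, adjusted p = 4.95e-19) and ibpB, a small heat shock protein gene, from 13.0 ± 9.25 to 780.2 ± 233 CPM (log2FC 6.41 ± 0.36, adjusted p = 6.31e-21). Each of the 12 sentinels rose, by log2FC of 1.93 (grpE) to 6.41 (ibpB) (20 of 20 on the list, list alone 20, camera FDR = 3.56e-70). At 60 min dnaK rose from 2486 ± 240.02 to 7770.5 ± 1409 CPM (log2FC 1.64 ± 0.21, adjusted p = 4.47e-08). 11 of the 12 sentinel genes rose, by log2FC of 0.84 (grpE) to 1.95 (ibpB), while groS was not called (log2FC 1.16 ± 0.48, adjusted p = 0.250) (15 of 20 on the list, list alone 19, camera FDR = 1.48e-35). The arabinose genes araH, araE and araG were the 3 highest at 15 min. RNA polymerase genes were higher at 15 min (4 of 8, list alone 4, camera FDR = 0.0403, adjusted p = 0.366 with estimated correlation), among them rpoC (log2FC 1.17 ± 0.24, adjusted p = 0.000468), as was the cold shock helicase gene deaD (log2FC 2.29 ± 0.26, adjusted p = 5.68e-10). The lowest at 15 min were aldB, rdgC and gadW (log2FC -1.85 to -2.24), and pyrimidine genes were lower (4 of 9, list alone 5, camera FDR = 0.00518), such as pyrC (log2FC -1.34 ± 0.23, adjusted p = 2.94e-05). At 60 min the lowest were slp, ydeN, the methionine synthesis gene metE and the maltose uptake genes malE and malF (-2.16 to -2.32). malE fell from 899 ± 63.9 to 202 ± 20.1 CPM (log2FC -2.16 ± 0.25, adjusted p = 3.84e-09), within 6 of 25 alternative sugar uptake genes (list alone 8, camera FDR = 3.98e-09). At 15 min 338 genes were called (219 higher and 119 lower, 29% without overlap). The count was 191 without H3 replicate 1, 219 without pSB1C3 replicate 2 and 183 without pSB1C3 replicate 3. At 60 min 91 genes were called (63 higher and 28 lower, 22.2% without overlap). The count was 51 without H3 replicate 1, 57 without pSB1C3 replicate 3 and 154 without the 3 shallow libraries. Calls were lost at 15 min for gadW without H3 replicate 2 or 3 or pSB1C3 replicate 2 or 3 (adjusted p 0.0559 to 0.0857). Lost at 60 min were slp without H3 replicate 1 or 3 or pSB1C3 replicate 2 (adjusted p 0.0928 to 0.134). grpE was lost without H3 replicate 1 or pSB1C3 replicate 2 or 3 (adjusted p 0.0515 to 0.229). fxsA was lost without H3 replicate 1 or pSB1C3 replicate 2 (adjusted p 0.0515 to 0.116).

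With Lux in DH10B the small heat shock protein genes ibpA and ibpB were among the 5 highest genes at both times. At 15 min ibpB rose from 13.0 ± 9.25 to 6003 ± 538 CPM (log2FC 9.36 ± 0.37, adjusted p = 1.23e-27). The 12 sentinel genes all rose, by log2FC of 2.75 (grpE) to 9.36 (ibpB) (20 of 20 on the list, list alone 20, camera FDR = 9.15e-124). At 60 min ibpB rose from 37.9 ± 2.26 to 5165 ± 373 CPM (log2FC 7.09 ± 0.30, adjusted p = 2.79e-26). All 12 sentinel genes rose, by log2FC of 2.10 (grpE) to 7.09 (ibpB) (19 of 20 on the list, list alone 20, camera FDR = 6.36e-55). Acid resistance genes, which protect cells at low pH, were higher at 15 min (7 of 10, list alone 8, camera FDR = 3.75e-12), with gadC from 16.7 ± 6.13 to 154 ± 8.05 CPM (log2FC 3.44 ± 0.42, adjusted p = 5.82e-09), and lower at 60 min (6 of 10, list alone 6, camera FDR = 0.00890, adjusted p = 0.267 with estimated correlation). The lowest genes at 15 min were ynjE, yedE and yedF (-2.68 to -2.94). At 60 min the fry genes of a sugar phosphotransferase were lowest: fryC fell from 253 ± 49.8 to 8.23 ± 0.768 CPM (log2FC -4.91 ± 0.37, adjusted p = 5.79e-16), fryA and ypdE had -4.40 to -4.83, and fryB was lower by a ratio of 119 (95% counting interval 32.7 to 987). The sulfate gene cysC was the other of the 5 (log2FC -4.29 ± 0.76, adjusted p = 7.70e-05). malE fell from 899 to 71.6 CPM (log2FC -3.65 ± 0.27, adjusted p = 4.98e-16), within 9 of 25 alternative sugar uptake genes (list alone 9, camera FDR = 6.41e-05). RpoS-dependent genes were lower (14 of 20, list alone 14, camera FDR = 6.13e-10), such as the catalase gene katE (log2FC -2.02 ± 0.28, adjusted p = 1.20e-07). Ribosomal protein genes were higher (32 of 52, list alone 38, camera FDR = 1.01e-11, adjusted p = 0.213 with estimated correlation), such as rpsH (log2FC 1.17 ± 0.20, adjusted p = 1.93e-05), and so were TCA cycle genes (6 of 14, list alone 7, camera FDR = 0.0124, adjusted p = 0.395 with estimated correlation). At 15 min 120 genes were called (90 higher and 30 lower, 18.4% without overlap), and 88 higher and 51 lower by DESeq2. At 60 min 553 genes were called (274 higher and 279 lower, 38.3% without overlap). The call of yedF at 15 min was lost without Lux replicate 1 or pSB1C3 replicate 3 (adjusted p 0.0953 to 0.0963).

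M1 in DH10B changed more genes than the other constructs there. At 15 min all 12 sentinel genes rose, by log2FC of 2.39 (hslU) to 6.57 (ibpB) (20 of 20 on the list, list alone 20, camera FDR = 5.74e-52). At 60 min dnaK rose from 2545 ± 441 to 23744 ± 1722 CPM (log2FC 3.22 ± 0.22, adjusted p = 1.87e-17) and ibpB from 28.4 ± 12.5 to 2349 ± 189.8 CPM (log2FC 6.31 ± 0.30, adjusted p = 9.46e-24). Each of the 12 sentinels rose, by log2FC of 1.44 (groL) to 6.31 (ibpB) (20 of 20 on the list, list alone 20, camera FDR = 6.54e-32). Cold shock genes, which act on RNA structure, were higher at 15 min (5 of 7, list alone 6, camera FDR = 0.000186) and 60 min (7 of 7, list alone 7, camera FDR = 0.000119), when deaD rose from 183 ± 24.5 to 3877 ± 367 CPM (log2FC 4.40 ± 0.28, adjusted p = 6.45e-19). ycfJ had log2FC 5.06 ± 0.54, paoD, with no read in the 3 pLys libraries, was at least 11.1-fold higher, and the drpB ratio was 53.8 (95% counting interval 8.92 to 2197). Ribosomal protein genes were higher (28 of 52, list alone 32, camera FDR = 4.37e-09, adjusted p = 0.293 with estimated correlation at 15 min, 41 of 52, list alone 41, camera FDR = 4.18e-13, adjusted p = 0.172 with estimated correlation at 60 min), such as rpsE (log2FC 2.10 ± 0.22, adjusted p = 1.32e-11). Sugar uptake and central metabolism were lower. The galactose-binding protein gene mglB fell from 8817 ± 2092 to 174 ± 88.6 CPM (log2FC -5.65 ± 0.32, adjusted p = 1.12e-20), within 23 of 25 alternative sugar uptake genes (list alone 23, camera FDR = 1.64e-22), and 20 of 25, list alone 21, camera FDR = 2.76e-18 at 15 min. At 60 min glycolysis (13 of 13, list alone 13, camera FDR = 1.90e-09), the TCA cycle (14 of 14, list alone 14, camera FDR = 2.12e-10), ATP synthase (8 of 9, list alone 8, camera FDR = 1.21e-05, adjusted p = 0.236 with estimated correlation), aerobic respiration (13 of 20, list alone 13, camera FDR = 1.75e-05, adjusted p = 0.337 with estimated correlation) and RpoS-dependent genes (17 of 20, list alone 17, camera FDR = 1.17e-06, adjusted p = 0.0767 with estimated correlation) were lower, among them fbaA (log2FC -3.59 ± 0.26, adjusted p = 1.52e-16) and fumA (log2FC -2.90 ± 0.22, adjusted p = 2.62e-16). At 15 min fryC and ypdF were among the lowest (-4.81 to -5.94). 11 of 14 TCA cycle genes fell (list alone 12, camera FDR = 1.96e-11). The lowest genes had no read in the 3 M1 libraries: malK was at least 14.3-fold lower at 15 min, and at 60 min malK, ydcV, glcE and hdeB were at least 37.9-fold, 16.9-fold, 14.9-fold and 14.7-fold lower. malE was lower at 60 min by a ratio of 239.9 (95% counting interval 66.2 to 1984). At 15 min 684 genes were called (309 higher and 375 lower, 37.1% without overlap). At 60 min 1283 genes were called (580 higher and 703 lower, 51.2% without overlap). The median log2FC of all genes at 60 min was -0.03, 0.10 with RLE size factors and 0.11 by DESeq2.

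With LacZ in DH10B heat shock genes were not called at 15 min and were higher at 60 min. At 15 min dnaK was at 907 ± 107 CPM against 1045 ± 76.0 (log2FC -0.20 ± 0.21, adjusted p = 0.999) and fxsA, the sentinel with the smallest p, had log2FC -1.78 ± 0.53, adjusted p = 0.305. At 60 min dnaK rose from 1669 ± 249 to 8559.8 ± 324 CPM (log2FC 2.36 ± 0.21, adjusted p = 1.21e-12) and ibpB from 25.3 ± 2.29 to 738 ± 206 CPM (log2FC 4.85 ± 0.28, adjusted p = 3.82e-20). The 12 sentinel genes all rose, by log2FC of 1.16 (groL) to 4.85 (ibpB) (18 of 20 on the list, list alone 19, camera FDR = 5.06e-33, between 14 and 19 called under every other setting). Acid resistance genes were the lowest: gadC fell from 1088 ± 58.7 to 35.4 ± 8.16 CPM (log2FC -4.95 ± 0.34, adjusted p = 9.13e-17), and gadA, gadB, hdeB and hdeD had -4.36 to -4.85 (10 of 10, list alone 10, camera FDR = 1.39e-40). RpoS-dependent genes were lower (18 of 20, list alone 20, camera FDR = 4.08e-19), such as osmY (log2FC -2.42 ± 0.28, adjusted p = 1.30e-09), as were iron uptake genes (13 of 26, list alone 18, camera FDR = 6.89e-06, adjusted p = 0.163 with estimated correlation). Ribosomal protein genes were higher (41 of 52, list alone 46, camera FDR = 7.69e-24), such as rpsH (log2FC 1.28 ± 0.20, adjusted p = 4.43e-06). At 15 min 8 genes were called (2 higher and 6 lower, 9.73% without overlap), out of 94 with an unadjusted p under 0.05, and DESeq2 called 5 (2 higher and 3 lower). At 60 min 477 genes were called (217 higher and 260 lower, 35.1% without overlap). The count was 316 without LacZ replicate 1, 289 without pD864 replicate 1 and 280 without pD864 replicate 3. The call of groS at 60 min was lost without LacZ replicate 1 or 2 or any 1 pD864 library, with RLE size factors, with no count filter or by DESeq2 (adjusted p 0.0528 to 0.151).

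With H3 in MG1655 heat shock genes were higher at both times. At 15 min dnaK rose from 1171 ± 329.7 to 7805 ± 2001 CPM (log2FC 2.74 ± 0.23, adjusted p = 1.21e-12). All 12 sentinel genes rose, by log2FC of 1.63 (grpE) to 7.37 (ibpB) (19 of 20 on the list, list alone 20, camera FDR = 1.96e-67), and ibpB, ibpA and fxsA were the 3 highest genes. At 60 min dnaK rose from 2413 ± 404.5 to 8075 ± 1963 CPM (log2FC 1.74 ± 0.22, adjusted p = 1.90e-07). Each of the 12 sentinels rose, by log2FC of 0.99 (grpE) to 4.85 (ibpB) (16 of 20 on the list, list alone 18, camera FDR = 4.50e-43). Acid resistance genes were lower at 15 min (9 of 10, list alone 10, camera FDR = 5.44e-14) and 60 min (7 of 10, list alone 9, camera FDR = 2.01e-15). At 15 min slp fell from 66.7 ± 12.4 to 5.77 ± 3.31 CPM (log2FC -3.42 ± 0.42, adjusted p = 3.49e-08), and hdeA and hdeD had -3.15 to -3.17. At 60 min gadA fell from 71.0 ± 14.9 to 1.80 ± 3.11 CPM (log2FC -4.64 ± 0.69, adjusted p = 1.17e-05) and gadB, hdeB, gadE and hdeA had -2.54 to -3.45. RNA polymerase genes were higher at 15 min (4 of 8, list alone 4, camera FDR = 2.46e-05), such as rpoC (log2FC 1.08 ± 0.15, adjusted p = 9.42e-07). At 60 min the sulfate genes cysW and cysC and the enterobactin gene entC were among the 5 highest (3.23 to 3.44), with wide spread (entC 89.0 ± 90.7 CPM), within 5 of 27 Fur-regulated iron genes (list alone 16, camera FDR = 4.11e-10, adjusted p = 0.104 with estimated correlation) for entC. The citrate synthase gene gltA rose from 1326 to 3188 CPM (log2FC 1.27 ± 0.15, adjusted p = 8.70e-08), within 5 of 14 TCA cycle genes (list alone 12, camera FDR = 1.39e-11). At 15 min 225 genes were called (124 higher and 101 lower, 25.7% without overlap). The count was 149 without H3 replicate 1, 118 without pSB1C3 replicate 1, 132 without H3 replicate 2 and 371 with a replicate block. At 60 min 124 genes were called (86 higher and 38 lower, 19.9% without overlap). The count was 61 without pSB1C3 replicate 1, 72 without H3 replicate 2, 78 without pSB1C3 replicate 3, 228 with a replicate block and 80 in a fit of those groups alone. At 15 min the call of hdeD was lost without any 1 of the 6 libraries or with no count filter (adjusted p 0.0616 to 0.207). At 60 min calls were lost for cysC without any 1 pSB1C3 library or H3 replicate 2, with no count filter or in a fit of those groups alone (adjusted p 0.0519 to 0.424). cysW was lost without pSB1C3 replicate 1 or 3 or H3 replicate 2 (adjusted p 0.0555 to 0.138). entC was lost without H3 replicate 2 or in a fit of those groups alone (adjusted p 0.0764 to 0.122). hdeB and hdeA were lost without any 1 of the 6 libraries or with no count filter (adjusted p 0.0510 to 0.202). groS was lost without any 1 pSB1C3 library (adjusted p 0.0510 to 0.0937). fxsA was lost without pSB1C3 replicate 2 or 3 or H3 replicate 3 (adjusted p 0.0638 to 0.438).

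With Lux in MG1655 heat shock genes were also higher. At 15 min ibpB rose from 2.42 ± 2.48 to 552 ± 48.9 CPM (log2FC 7.59 ± 0.79, adjusted p = 4.68e-08). The 12 sentinel genes all rose, by log2FC of 1.20 (lon) to 7.59 (ibpB) (13 of 20 on the list, list alone 16, camera FDR = 8.65e-49). At 60 min ibpB rose from 6.69 ± 3.86 to 1126 ± 196 CPM (log2FC 7.18 ± 0.70, adjusted p = 2.65e-08). 11 of the 12 sentinel genes rose, by log2FC of 1.39 (lon) to 7.18 (ibpB), while fxsA was not called (log2FC 1.26 ± 0.41, adjusted p = 0.0703) (13 of 20 on the list, list alone 18, camera FDR = 9.82e-46). At 15 min arpB was the other of the 3 highest genes (log2FC 3.24 ± 0.79, adjusted p = 0.00797), and the glycolate genes glcD and glcE were, with araE, the lowest (-3.38 to -4.29). TCA cycle genes were lower at 15 min (12 of 14, list alone 14, camera FDR = 9.99e-21), such as gltA (from 3272 to 1632 CPM, log2FC -1.003 ± 0.15, adjusted p = 2.59e-06), as were alternative sugar uptake genes (11 of 27, list alone 15, camera FDR = 9.77e-17). At 60 min gltA was higher (from 1326 to 2553 CPM, log2FC 0.94 ± 0.15, adjusted p = 1.22e-05). The tryptophanase operon genes tnaA and tnaB and the porin gene phoE were among the highest at 60 min (2.71 to 2.85), and acid resistance genes were higher (6 of 10, list alone 10, camera FDR = 1.29e-10), such as gadC (log2FC 1.88 ± 0.38, adjusted p = 0.00118). The NAD synthesis gene nadB fell from 249.7 ± 50.9 to 28.4 ± 9.05 CPM (log2FC -3.11 ± 0.58, adjusted p = 0.000866), and pnuC, nirB, csdE and flhE had -2.16 to -2.53. Flagellar genes were lower (20 of 52, list alone 30, camera FDR = 4.61e-23), such as flgA (log2FC -0.93 ± 0.19, adjusted p = 0.00128). At 15 min 107 genes were called (40 higher and 67 lower, 18.9% without overlap). The count was 66 without pSB1C3 replicate 1 and 162 in a fit of those groups alone. At 60 min 130 genes were called (88 higher and 42 lower, 19.99% without overlap). The count was 78 without pSB1C3 replicate 2 and 76 without Lux replicate 2. Calls were lost at 15 min for glcE without pSB1C3 replicate 1 or 3 or Lux replicate 1 or 3 or with no count filter (adjusted p 0.0782 to 0.273). arpB was lost without pSB1C3 replicate 1 or Lux replicate 3 (adjusted p 0.0622 to 0.0660). groS was lost without pSB1C3 replicate 1 or 3 or Lux replicate 2 (adjusted p 0.0751 to 0.0897). Lost at 60 min were nirB without any 1 Lux library or pSB1C3 replicate 2, with no count filter or in a fit of those groups alone (adjusted p 0.0558 to 0.417). flhE was lost without any 1 Lux library or pSB1C3 replicate 2 or 3 or with no count filter (adjusted p 0.0596 to 0.204). phoE was lost without pSB1C3 replicate 1 or 2 or Lux replicate 1 or 2 (adjusted p 0.0609 to 0.146). tnaA was lost without pSB1C3 replicate 1 or 3 or Lux replicate 2 (adjusted p 0.0704 to 0.100). csdE was lost without pSB1C3 replicate 1 or 2 or any 1 Lux library (adjusted p 0.0618 to 0.152).

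M1 in MG1655 again changed the most genes. At 15 min ibpB rose from 2.06 ± 2.25 to 4368 ± 1427 CPM (log2FC 11.02 ± 0.84, adjusted p = 3.76e-11). All 12 sentinel genes rose, by log2FC of 2.10 (lon) to 11.02 (ibpB) (20 of 20 on the list, list alone 20, camera FDR = 5.33e-55). At 60 min dnaK rose from 2790.4 ± 116 to 22079 ± 905 CPM (log2FC 2.98 ± 0.23, adjusted p = 4.76e-15) and ibpA from 44.0 ± 23.3 to 14873 ± 3718 CPM (log2FC 8.37 ± 0.62, adjusted p = 2.80e-12). Each of the 12 sentinels rose, by log2FC of 1.49 (groS) to 9.47 (ibpB) (20 of 20 on the list, list alone 20, camera FDR = 1.78e-24). Cold shock genes were higher at 15 min (6 of 7, list alone 7, camera FDR = 4.29e-06) and 60 min (7 of 7, list alone 7, camera FDR = 2.46e-05): cspA rose from 116 to 2379 CPM (log2FC 4.34 ± 0.59, adjusted p = 2.45e-06) and from 50.2 ± 3.18 to 1497 ± 614 CPM (log2FC 4.90 ± 0.63, adjusted p = 2.03e-07), cspB had 3.94 ± 0.69 and the cspG ratio was 79.5 (95% counting interval 21.5 to 666) at 60 min. Ribosomal protein genes were higher (42 of 54, list alone 47, camera FDR = 1.48e-28 at 15 min, 42 of 54, list alone 44, camera FDR = 3.81e-11, adjusted p = 0.172 with estimated correlation at 60 min), such as rplR (log2FC 1.41 ± 0.18, adjusted p = 1.30e-08). Flagella and chemotaxis genes, needed for swimming, were lowest at 60 min (47 of 52, list alone 48, camera FDR = 1.40e-46): flgE fell from 1398 ± 170.5 to 14.1 ± 18.1 CPM (log2FC -6.88 ± 0.42, adjusted p = 1.10e-15), flgB had -6.39 ± 0.44, and flgF, with no read in the 3 M1 libraries, was at least 74.0-fold lower. The enterobactin esterase gene fes was at least 14.9-fold lower (19 of 27 Fur-regulated iron genes (list alone 21, camera FDR = 0.00156, adjusted p = 0.473 with estimated correlation)) and ycaC had -6.45 ± 0.52. Glycolysis (13 of 13, list alone 13, camera FDR = 4.77e-10), RpoS-dependent genes (20 of 21, list alone 20, camera FDR = 3.12e-13), acid resistance (9 of 10, list alone 9, camera FDR = 0.000672, adjusted p = 0.310 with estimated correlation) and alternative sugar uptake (17 of 27, list alone 19, camera FDR = 3.91e-06) were also lower, with tpiA (log2FC -2.76 ± 0.20, adjusted p = 5.59e-16). The lowest at 15 min were gabP and ddpX (-2.69 to -2.95) and rutA, by a ratio of 7.83 (95% counting interval 2.50 to 39.5). At 15 min 573 genes were called (274 higher and 299 lower, 32.3% without overlap). At 60 min 1311 genes were called (600 higher and 711 lower, 51.7% without overlap). Calls were lost at 15 min for rutA without M1 replicate 1 or pLys replicate 3 (adjusted p 0.0503 to 0.0681).

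With LacZ in MG1655 few host genes changed. At 60 min dnaJ, a cochaperone of DnaK, was the only sentinel called (from 162 to 309 CPM, log2FC 0.93 ± 0.21, adjusted p = 0.00932). dnaK was at 4234 ± 337 CPM against 2536 ± 377 (log2FC 0.74 ± 0.21, adjusted p = 0.0700), and the other 10 had log2FC of 0.18 to 2.55 (adjusted p 0.0598 for htpG to 0.868 for groS). The list count was 1 of 20, list alone 9, camera FDR = 2.36e-07, adjusted p = 0.126 with estimated correlation. With the replicate number as a block 8 heat shock genes were called, 3 by DESeq2, 2 without pD864 replicate 3, and none in a fit of those groups alone or without pD864 replicate 1. At 15 min no sentinel was called, and lon had the smallest p (log2FC 0.41 ± 0.17, adjusted p = 0.485). Apart from the lac genes, ydjO (log2FC 2.25 ± 0.58, adjusted p = 0.0366) and the cystine transporter gene tcyP (log2FC 1.66 ± 0.41, adjusted p = 0.0367) were highest at 60 min. Acid resistance genes were lower (4 of 10, list alone 9, camera FDR = 4.39e-09, adjusted p = 0.0566 with estimated correlation), such as gadA (log2FC -1.67 ± 0.39, adjusted p = 0.0188). nadB was lower at 15 min (from 94.8 to 11.7 CPM, log2FC -3.02 ± 0.67, adjusted p = 0.0156). At 15 min 21 genes were called (10 higher and 11 lower, 12.8% without overlap). The count was 13 without pD864 replicate 1, 12 without LacZ replicate 3, 33 with a replicate block and 12 in a fit of those groups alone. At 60 min 41 genes were called (16 higher and 25 lower, 14.8% without overlap). The count was 17 without pD864 replicate 1, 25 without LacZ replicate 2, 17 without LacZ replicate 3, 97 with a replicate block and 16 in a fit of those groups alone. Calls were lost at 15 min for nadB without pD864 replicate 1 or LacZ replicate 2 or 3 or in a fit of those groups alone (adjusted p 0.131 to 0.579). Lost at 60 min were dnaJ without pD864 replicate 1 or in a fit of those groups alone (adjusted p 0.119 to 0.233). tcyP was lost without any 1 pD864 library or LacZ replicate 2 or 3 or with no count filter (adjusted p 0.0534 to 0.227). ydjO was lost without LacZ replicate 2 or 3 or pD864 replicate 2 or 3 or in a fit of those groups alone (adjusted p 0.0762 to 0.182). gadA was lost without LacZ replicate 3 or pD864 replicate 3 or in a fit of those groups alone (adjusted p 0.0844 to 0.182).

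**Figure D1:**
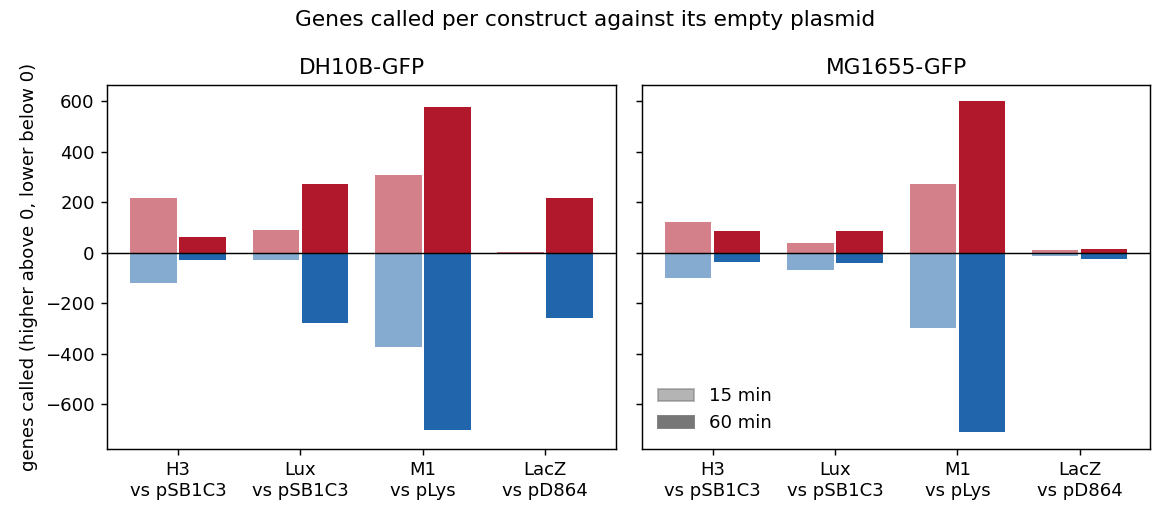
Genes called higher and lower at adjusted p under 0.05 in each comparison of a construct with its empty plasmid, by strain and time.

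The average of the 4 construct effects at 60 min, which asks for their mean and not whether each agrees, was high for heat shock genes in both strains. In DH10B ibpB had log2FC 5.05 ± 0.18, ibpA 4.76 ± 0.16, dnaJ 2.59 ± 0.15, htpG 2.56 ± 0.13 and dnaK 2.55 ± 0.13 (20 of 20, list alone 20, camera FDR = 4.67e-54). In MG1655 ibpB had 6.01 ± 0.43, ibpA 4.68 ± 0.34, fxsA 1.95 ± 0.24, hslR 1.89 ± 0.15 and dnaK 1.85 ± 0.13 (20 of 20, list alone 20, camera FDR = 1.32e-47). The other highest genes with the same direction in all 4 constructs were araE (above ibpB), araF, araG, ycjX and mutM in DH10B (2.54 to 5.82) and ydjO, cysW, cysU and cspA in MG1655 (1.89 to 2.36). The lowest in DH10B included the porin gene ompC (log2FC -2.68 ± 0.17, adjusted p = 3.15e-18), metE, the biotin gene bioB, slp and ycaC (-2.41 to -2.64), besides hdeB, hdeA, yegP, yeaH and ydcV, which had 3 or fewer reads with M1. In MG1655 grcA, ycaC, yegP, bioB, nirB, nadB, katE and sra were lowest (-1.59 to -2.45). In DH10B 1192 genes were called (504 higher and 688 lower). The count was 761 without replicate 1 of every group. In MG1655 780 genes were called (315 higher and 465 lower). The count was 430 without replicate 1 and 515 without 3. In MG1655 calls were lost for cysU without replicate 2 (adjusted p = 0.103). grcA was lost without replicate 1 (adjusted p = 0.0620).

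Among gene lists in the DH10B average, higher groups were ribosomal proteins (49 of 52 higher, list alone 49, camera FDR = 5.65e-21), cold shock (5 of 7 higher, list alone 7, camera FDR = 0.000433), translation factors (6 of 11 higher, list alone 6, camera FDR = 0.0173, adjusted p = 0.206 with estimated correlation) and RNA polymerase and sigma factors (4 of 8 higher and 1 lower, list alone 4, camera FDR = 0.0466, adjusted p = 0.296 with estimated correlation), with rpsH (log2FC 1.20 ± 0.12, adjusted p = 3.99e-12) and deaD (log2FC 2.29 ± 0.15, adjusted p = 2.81e-18) as examples. Lower groups were RpoS-dependent genes (19 of 20 lower, list alone 19, camera FDR = 5.80e-14), acid resistance (10 of 10 lower, list alone 10, camera FDR = 1.26e-09), alternative sugar uptake (22 of 25 lower, list alone 24, camera FDR = 2.35e-14) and glycolysis and PTS (11 of 13 lower, list alone 12, camera FDR = 7.02e-06). Also lower were ribosome hibernation (4 of 4 lower, list alone 4, camera FDR = 0.0113, adjusted p = 0.0619 with estimated correlation), oxidative stress (7 of 11 lower, list alone 7, camera FDR = 0.0256, adjusted p = 0.0583 with estimated correlation), Fur-regulated iron genes (12 of 26 lower and 1 higher, list alone 12, camera FDR = 0.0270, adjusted p = 0.3997 with estimated correlation), RpoE envelope stress (7 of 15 lower, list alone 8, camera FDR = 0.0380, adjusted p = 0.206 with estimated correlation) and Cpx envelope stress (6 of 10 lower, list alone 6, camera FDR = 0.0398, adjusted p = 0.137 with estimated correlation), with katE (log2FC -2.22 ± 0.16, adjusted p = 4.40e-17) and the hibernation factor gene rmf (log2FC -1.44 ± 0.36, adjusted p = 0.00142) as examples. Not passing camera were phage shock (3 higher and 1 lower of 7, FDR 0.275), SOS response (1 higher and 1 lower of 14, FDR 0.680), anaerobic metabolism (1 higher and 6 lower of 15, FDR 0.395), amino acid biosynthesis (2 higher and 7 lower of 40, FDR 0.278), purine synthesis (3 higher and 2 lower of 14, FDR 0.456), flagella and chemotaxis (2 higher of 5, FDR 0.278) and toxin-antitoxin (5 higher of 18, FDR 0.178). All of these but SOS response and purine synthesis passed fry (adjusted p at most 0.00443). In MG1655 flagella and chemotaxis (44 of 52 lower, list alone 45, camera FDR = 4.00e-43), RpoS-dependent genes (17 of 21 lower, list alone 18, camera FDR = 1.24e-15) and glycolysis and PTS (11 of 13 lower, list alone 12, camera FDR = 2.61e-06) were lower, and cold shock genes (5 of 7 higher, list alone 6, camera FDR = 0.000302) and ribosomal proteins (31 of 54 higher, list alone 34, camera FDR = 2.86e-10, adjusted p = 0.125 with estimated correlation) higher. In DH10B rmf was lost without replicate 1 of every group (adjusted p = 0.0926).

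**Figure D2:**
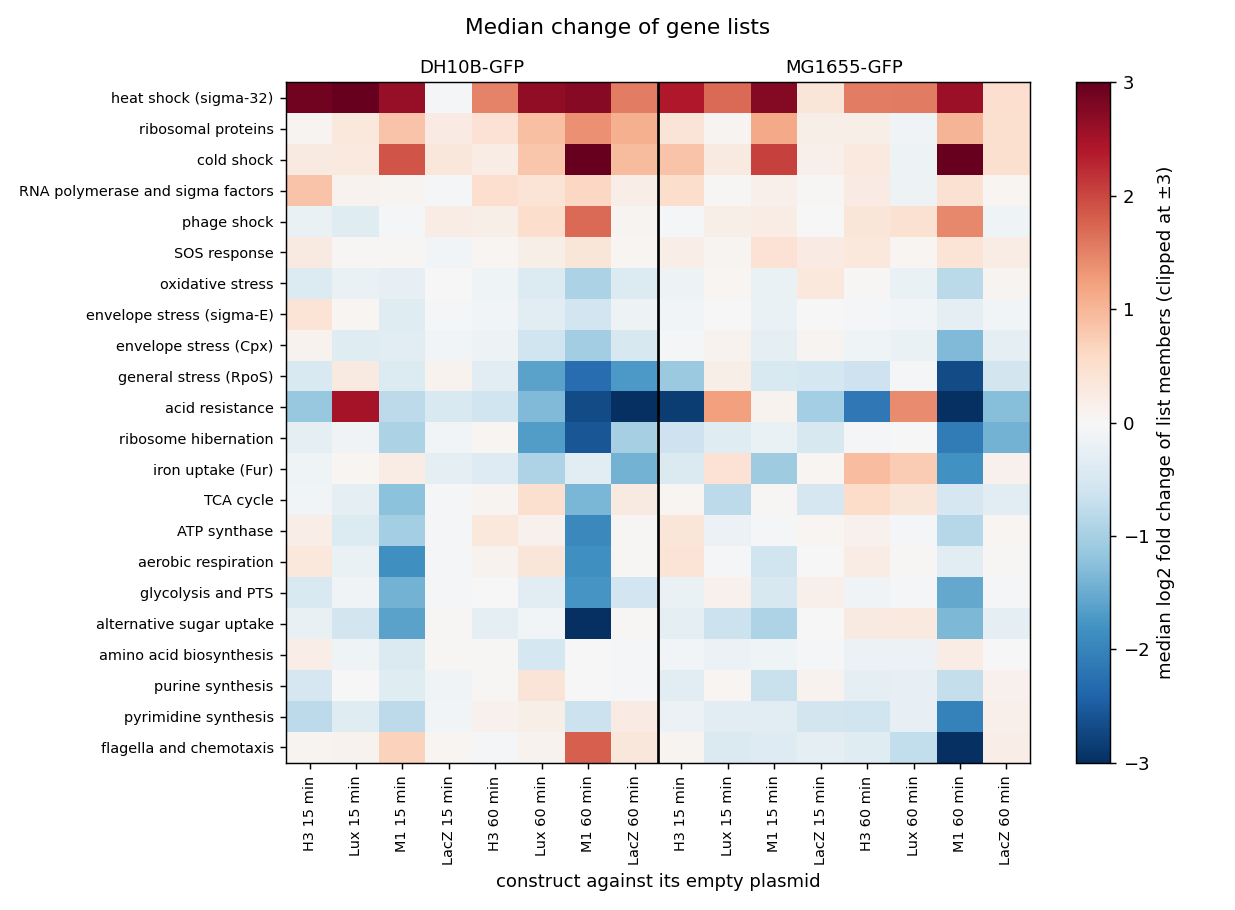
Median log2 fold change of 22 gene lists in the 16 comparisons of a construct with its empty plasmid, drawn in colour up to 3 in either direction.

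At 60 min pairs of constructs shared more called genes, higher and lower, than independent calls would give, except the lower genes of Lux and LacZ in MG1655 (3 higher and 0 lower against 0.470 and 0.350 expected, 5 higher with Lux and lower with LacZ, correlation across genes 0.0479). Of the 28 genes called higher in all 4 constructs in DH10B, 11 were sentinels, and araE, deaD, mutM, rplR, topA and ycjX were others. The 5 called lower were accB, bioB, gadW, metE and ompC. In MG1655 dnaJ was the only gene called in all 4. Lux and M1, with different empty plasmids, shared 176 higher and 214 lower against 53.4 and 65.8 expected in DH10B. In MG1655 it was 49 and 35 against 17.5 and 9.92. Between M1 and LacZ it was 155 and 169 against 42.2 and 61.4 in DH10B and 11 and 9 against 3.19 and 5.90 in MG1655. Some were opposite: 22 higher with Lux and lower with M1 in DH10B, 18 higher with H3 and lower with M1 in MG1655. H3 and Lux share the pSB1C3 libraries: 54 and 24 against 5.79 and 2.62 in DH10B and 32 and 7 against 2.51 and 0.530 in MG1655. Their log2FC had covariance 0.384 and 0.189, above 0.088 ± 0.0064 and 0.0966 ± 0.007 in 20 simulations per strain sharing only controls. None had a shared call, nor a construct effect to call. Correlations were 0.627 and 0.466 (simulated 0.454 and 0.466). Genes are not independent replicates.

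The construct effect was then compared between 60 and 15 min. In DH10B the effect on acid resistance and RpoS-dependent genes was lower at 60 than at 15 min: gadA (difference in log2FC -2.87 ± 0.41, adjusted p = 1.00e-06), gadC (-2.76 ± 0.34, 6.73e-08), 8 of 10 acid resistance genes (list alone 10, camera FDR = 4.51e-16) and 13 of 20 RpoS-dependent genes (list alone 17, camera FDR = 1.52e-24). hdeB, appC and glsA were the others of the 5 lowest but had 3 or fewer reads in some groups. The LacZ control pD864 was higher in acid resistance genes than cells without a plasmid at 60 min. Ribosomal protein genes (19 of 52 higher, list alone 25, camera FDR = 4.09e-19, adjusted p = 0.0745 with estimated correlation) went the other way. The highest were yecF, pdeL, qseC, folK and uxaC (1.41 to 1.81). In MG1655 the effect on flagella and chemotaxis genes was lower at 60 min (34 of 52, list alone 43, camera FDR = 1.08e-47), with fliF -1.53 ± 0.21 (adjusted p = 2.28e-06) and flgE -1.52 ± 0.24 (4.33e-05), and yiaG had -1.56 ± 0.46. flgF and intG were also among the lowest 5, with 3 or fewer reads in some groups. The highest were phoE, tnaB, ydjO, tsuB and tsuA (1.71 to 2.46). In DH10B 225 genes were called (77 higher and 148 lower). The count was 62 without replicate 1 of every group and 82 without replicate 3. In MG1655 116 genes were called (44 higher and 72 lower). The count was 35 without replicate 1 and 46 without 3. Calls were lost in DH10B for yecF without replicate 1 or 2 (adjusted p 0.208 to 0.359). pdeL and qseC were lost without replicate 1, 2 or 3 or with no count filter (adjusted p 0.0562 to 0.427). folK was lost without replicate 3 (adjusted p = 0.564). uxaC was lost without replicate 1 (adjusted p = 0.289). In MG1655 calls were lost for phoE and tnaB without replicate 2 or 3 (adjusted p 0.0874 to 0.319). ydjO was lost without replicate 2 (adjusted p = 0.149). tsuB, tsuA and yiaG were lost without replicate 1, 2 or 3 (adjusted p 0.0510 to 0.304).

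Tests of the difference between strains (MG1655 minus DH10B, 60 min) asked whether each construct acted alike in both. All 5 arabinose genes tested were called lower with H3, Lux and M1. araE, araF, araG, araH and araJ had -5.27 to -9.44 with H3 and -5.56 to -10.19 with Lux, and araE -8.47 ± 0.51 with M1. With H3 the highest were sbp, entC, cysW, yciW and cysH (4.08 to 6.25). With Lux acid resistance genes were higher in MG1655 relative to DH10B (9 of 10, list alone 9, camera FDR = 1.10e-09), RpoS-dependent genes too (8 of 20, list alone 13, camera FDR = 1.00e-08), and heat shock genes lower (7 of 20, list alone 12, camera FDR = 8.66e-08, adjusted p = 0.0659 with estimated correlation), with dnaK (log2FC -1.04 ± 0.29, adjusted p = 0.0144). malK, yciW and fryA had 5.02 to 5.21, and fryC and ypdE were also among the 5 highest, with 3 or fewer reads in both MG1655 groups. With M1 lamB and fryA had 5.56 to 5.82. The others of the 5 highest (fryC, xylF and glcA) and, beside araE, of the 5 lowest (fliK, fliN, flgE and fes) had 3 or fewer reads in a group. TCA cycle (10 of 14, list alone 12, camera FDR = 3.93e-12) and alternative sugar uptake genes (11 of 25, list alone 11, camera FDR = 1.57e-09) were higher, such as gltA (log2FC 2.16 ± 0.25, adjusted p = 8.07e-11). With LacZ heat shock genes were lower (7 of 20, list alone 12, camera FDR = 9.02e-18), with ibpA (log2FC -2.96 ± 0.52, adjusted p = 0.000182) and dnaK (log2FC -1.61 ± 0.29, adjusted p = 0.000191), and acid resistance genes higher (9 of 10, list alone 10, camera FDR = 9.79e-24), with gadC, gadB, hdeB and hdeD 3.21 to 3.44 and yjdJ, which had few reads. The tryptophan genes trpE, trpD, mtr and trpC (-4.84 to -8.38) rested on pD864 replicate 1 in MG1655. With H3 43 genes differed (32 higher and 11 lower), 12 without replicate 1 of every group and 12 without replicate 3. With Lux 240 did (134 and 106), 72 without replicate 1 and 48 without 3. With M1 317 did (179 and 138), 141 without replicate 1 and 156 without 3. With LacZ 52 did (31 and 21), 6 without replicate 1, 91 without replicate 2, 12 without replicate 3, 90 by DESeq2 and 81 without the 3 shallow libraries. Calls were lost with H3 for sbp, cysW, yciW and cysH without replicate 1 or 3 or in a fit of those groups alone (adjusted p 0.306 to 0.525). entC was lost without replicate 1 or 2 (adjusted p 0.112 to 0.360). With Lux calls were lost for yciW without replicate 1 or 3 (adjusted p 0.0863 to 0.102). fryA was lost without replicate 3 (adjusted p = 0.0993). With LacZ calls were lost for trpE without replicate 1 or in a fit of those groups alone (adjusted p 0.143 to 0.901). trpD, mtr and trpC were lost without replicate 1 or 3 or in a fit of those groups alone (adjusted p 0.0550 to 0.964). hdeB and hdeD were lost without replicate 1 or 3 (adjusted p 0.0941 to 0.349). dnaK was lost without replicate 3 (adjusted p = 0.0531).

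Empty plasmids in DH10B were compared with cells without a plasmid, whose inducer the labels leave open. Galactose uptake and breakdown genes were among the highest with pSB1C3 and pLys at 15 min: mglC rose from 87.8 ± 8.25 to 605 ± 37.9 CPM (log2FC 2.79 ± 0.29, adjusted p = 9.58e-10) with pSB1C3 and from 87.8 to 494 CPM (log2FC 2.48 ± 0.29, adjusted p = 2.24e-08) with pLys, and galT and galS had 2.19 to 2.63 and 2.15 to 2.38. The alternative sugar uptake list gave 6 of 25, list alone 6, camera FDR = 1.43e-18 with pSB1C3 and 6 of 25, list alone 6, camera FDR = 2.44e-06 with pLys, where its median was negative and its mean and test positive. galK was also higher with pSB1C3 (log2FC 2.14 ± 0.28, adjusted p = 2.25e-07) and uxaC with pLys (log2FC 1.91 ± 0.44, adjusted p = 0.0146). The iron genes fhuA (pSB1C3 -1.85 ± 0.45, pLys -2.38 ± 0.44) and fhuF (pLys -2.89 ± 0.64), bcp with pSB1C3 (-1.03 ± 0.24), and gadA, hdeD and ykgF with pLys (-1.26 to -2.34) were lower. With pD864 rhamnose genes were highest: rhaB, rhaT, rhaD and rhaS had 6.79 to 10.24 (7 of 7, list alone 7, camera FDR = 9.08e-264), the rhaA ratio was 5439 (95% counting interval 976 to 214882) and rhaM was at least 179.5-fold higher. The lowest were mglB (log2FC -1.76 ± 0.26, adjusted p = 6.73e-06), efeO, fhuA, galS and mglC (-1.52 to -2.19). The count at 15 min was 12 (10 higher and 2 lower) for pSB1C3 (9 higher with RLE size factors, 9 higher and 4 lower by DESeq2, 7 without no-plasmid replicate 3). For pLys the count was 16 (11 higher and 5 lower) (11 higher and 8 lower with RLE size factors, 14 higher and 13 lower by DESeq2, 28 in a fit of those groups alone and 31 without the 3 shallow libraries), and for pD864 17 (8 higher and 9 lower) (11 without pD864 replicate 1, 11 without no-plasmid replicate 1, 10 without pD864 replicate 2 and 9 without no-plasmid replicate 3). Calls were lost with pSB1C3 for fhuA without any 1 pSB1C3 library or no-plasmid replicate 1 or 3, with RLE size factors, with no count filter, with all gene rows kept, with a replicate block, in a fit of those groups alone or without the 3 shallow libraries (adjusted p 0.0571 to 0.600). bcp was lost without any 1 pSB1C3 library or no-plasmid replicate 1 or 3 or with RLE size factors (adjusted p 0.0622 to 0.209). With pLys calls were lost for uxaC without no-plasmid replicate 1 or 2 or pLys replicate 2 (adjusted p 0.0840 to 0.223). fhuF was lost without pLys replicate 1 or 3 or no-plasmid replicate 1 or 3 (adjusted p 0.0848 to 0.276). gadA was lost without pLys replicate 1 or 2 or no-plasmid replicate 1 or in a fit of those groups alone (adjusted p 0.0721 to 0.326). hdeD was lost without any 1 pLys library or no-plasmid replicate 3 (adjusted p 0.0571 to 0.287). ykgF was lost without pLys replicate 2 or 3 or no-plasmid replicate 3 or in a fit of those groups alone (adjusted p 0.0730 to 0.392). With pD864 calls were lost for efeO and fhuA without any 1 pD864 library or no-plasmid replicate 1 or 3 or without the 3 shallow libraries (adjusted p 0.0512 to 0.623). galS was lost without pD864 replicate 1 or 2 or no-plasmid replicate 3 (adjusted p 0.103 to 0.355). mglC was lost without pD864 replicate 1 or 2 or no-plasmid replicate 2 or 3 (adjusted p 0.0603 to 0.174).

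At 60 min lac and galactose genes were among the highest with pSB1C3 and pLys. lacY, galT, melA and lacA had 3.22 to 4.61 with pSB1C3 and 2.36 to 3.78 with pLys. galT rose from 51.4 ± 24.2 to 555 ± 147 CPM (log2FC 3.28 ± 0.33, adjusted p = 5.24e-10) with pSB1C3. Acid resistance genes were lower with pSB1C3 (9 of 10, list alone 9, camera FDR = 4.97e-19) and pLys (8 of 10, list alone 9, camera FDR = 3.49e-12), such as gadC (log2FC -1.74 ± 0.34, adjusted p = 0.000582), and higher with pD864 (8 of 10, list alone 8, camera FDR = 2.20e-18), such as gadC (log2FC 3.32 ± 0.31, adjusted p = 3.14e-12). With pD864 rhaB, rhaA, rhaT, rhaM and rhaS had 4.98 to 9.53 (7 of 7, list alone 7, camera FDR = 4.65e-87), and the rhaD ratio was 641 (95% counting interval 219 to 3110.01). Alternative sugar uptake was higher with pSB1C3 (6 of 25, list alone 8, camera FDR = 1.03e-12) and pLys (6 of 25, list alone 7, camera FDR = 0.000289, adjusted p = 0.102 with estimated correlation, with a negative list median) and lower with pD864 (14 of 25, list alone 16, camera FDR = 8.03e-17), such as mglB (log2FC -2.38 ± 0.27, adjusted p = 2.18e-09). The lowest were ydcD, ariR, appY, ydjO and yeaC with pSB1C3 (-3.64 to -4.15), rhaA (no read with pLys, at least 4.60-fold lower), ymgA, ydcD, ariR and appY with pLys (-3.77 to -4.43) and yeaC, arfA, yobD, ydcD and tnpX with pD864 (-3.32 to -3.86). These 15 calls were lost without no-plasmid replicate 2, shallow and unlike replicates 1 and 3 (chi-square per gene 80.9 and 73.0, 5.31 between those; rRNA 41.0% against 71.4% and 76.4%) (adjusted p 0.0729 to 0.988), and some also under other settings. With pSB1C3 these were ydcD, ariR and ydjO without any 1 pSB1C3 library (adjusted p 0.0550 to 0.124). appY and yeaC were lost in a fit of those groups alone (adjusted p 0.666 to 0.688). With pLys these were ydcD without pLys replicate 1 (adjusted p = 0.0627). ariR was lost without pLys replicate 3 (adjusted p = 0.0924). appY, lacA and melA were lost in a fit of those groups alone (adjusted p 0.237 to 0.409). rhaA was lost without any 1 pLys library (adjusted p 0.0602 to 0.136). With pD864 these were yeaC and tnpX in a fit of those groups alone (adjusted p 0.273 to 0.326). arfA was lost without pD864 replicate 3 or in a fit of those groups alone (adjusted p 0.0693 to 0.434). yobD was lost without pD864 replicate 3 (adjusted p = 0.0503). ydcD was lost without pD864 replicate 2 or 3 (adjusted p 0.0532 to 0.0636). The count at 60 min was 96 (33 higher and 63 lower) for pSB1C3 (24 higher and 81 lower with RLE size factors, 28 higher and 136 lower by DESeq2, 28 without pSB1C3 replicate 1, 230 without no-plasmid replicate 1, 37 without no-plasmid replicate 2, 49 without pSB1C3 replicate 3, 8 in a fit of those groups alone and 36 without the 3 shallow libraries). For pLys it was 204 (109 higher and 95 lower) (89 higher and 130 lower with RLE size factors, 100 higher and 180 lower by DESeq2, 63 without pLys replicate 1, 339 without no-plasmid replicate 1, 75 without no-plasmid replicate 2, 102 without pLys replicate 3, 3 in a fit of those groups alone and 74 without the 3 shallow libraries). For pD864 it was 244 (112 higher and 132 lower) (99 higher and 217 lower by DESeq2, 137 without pD864 replicate 1 and 23 in a fit of those groups alone). The median log2FC of all genes was 0.0317 (-0.07 with RLE size factors, -0.08 by DESeq2) with pSB1C3 and -0.00230 (-0.11 with RLE size factors, -0.12 by DESeq2) with pLys.

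Between 15 and 60 min in empty plasmids, which asks what changes over time without a construct, RpoS-dependent and heat shock genes were higher at 60 min in both strains. In DH10B RpoS-dependent genes (20 of 20, list alone 20, camera FDR = 3.75e-22), acid resistance genes (10 of 10, list alone 10, camera FDR = 7.13e-12), iron uptake genes (23 of 26, list alone 25, camera FDR = 5.45e-09) and heat shock genes (14 of 20, list alone 15, camera FDR = 5.28e-08) were higher, such as osmY (log2FC 2.28 ± 0.17, adjusted p = 2.16e-15) and dnaK (log2FC 1.30 ± 0.12, adjusted p = 2.08e-12). sbp, cbl, cysN and yegP had 2.99 to 4.25. Purine (14 of 14, list alone 14, camera FDR = 2.09e-12), TCA cycle (13 of 14, list alone 13, camera FDR = 6.77e-09) and ribosomal protein genes (46 of 52, list alone 48, camera FDR = 6.93e-17, adjusted p = 0.0577 with estimated correlation) were lower, and glcG, treC, treB, trpA and glcB were the lowest genes (-2.00 to -2.19). In MG1655 RpoS-dependent genes (20 of 21, list alone 20, camera FDR = 3.04e-33) and heat shock genes (12 of 20, list alone 13, camera FDR = 1.24e-10) were higher. yegP, grcA and nadB had 2.69 to 3.11, and the other 2 of the 5 highest were yciE, with few reads, and trpE, with 2347 CPM in pD864 replicate 1 at 60 min and at most 43.0 in the other empty-plasmid libraries. Flagella and chemotaxis (44 of 52, list alone 46, camera FDR = 1.68e-20) and TCA cycle genes (12 of 14, list alone 12, camera FDR = 1.40e-12) were lower, such as gltA (log2FC -0.87 ± 0.09, adjusted p = 2.03e-11), and the nitrogen genes glnK, amtB and nac and tnaA and tnaB were lowest (-3.10 to -4.47). In DH10B 1031 genes were called (553 higher and 478 lower). In MG1655 772 genes were called (381 higher and 391 lower). The count was 390 without replicate 1 of every group. In DH10B calls were lost for trpA without replicate 1 (adjusted p = 0.106). In MG1655 calls were lost for trpE without replicate 2 or 3 (adjusted p 0.130 to 0.261).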

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

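The tests on arabinose genes were chosen after the result was seen. In DH10B the summed arabinose uptake genes araE, araF, araG, araH and araJ stood at 16089 ± 1935 CPM with H3, 15492 ± 1240.4 with Lux and 571 ± 76.0 with M1 at 60 min, against 77.8 ± 7.98 with pSB1C3 and 70.5 ± 25.7 with pLys. A mislabelled sample would put a library of 1 side at the level of the other, but the lowest construct library was 5.24 times the highest empty one, which argues against it. The inducer alone would raise empty plasmids as well, yet they held at most 0.865% of the level of their construct with H3 and Lux and, at 15 min, M1; with M1 at 60 min it was 12.4%, over the bound set, which left out the level without arabinose. There pLys stood above pD864 in rhamnose (58.1 ± 2.59) by 2.43% of what M1 did (at most 9.004% over single libraries). For araC supplied by the arabinose-induced constructs, araC was called higher in 2 of 6 comparisons in MG1655 (log2 fold change with H3 and M1 at 60 min 2.04 and 3.83) and not with Lux at 60 min (1.30) or with H3, Lux and M1 at 15 min (0.70, -0.49 and 0.82; for Lux adjusted p = 0.786). That is within the bound of 3 or fewer set against it, but the bound took missing calls for absence and DH10B has no araC row, so it cannot be told apart from another effect of construct expression.

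M1 called the most genes at 60 min in both strains. M1 libraries were among the shallowest, so thinning all to 1 depth (that of an M1 library in DH10B) did not test depth. M1 still called 2.51 times the genes of the next construct in DH10B (1178 against 470) and 9.73 times in MG1655 (1129 against 116). Without the 33 and 30 highest genes the ratios were 2.33 and 10.5, which argues against a few genes taking most of the counts. Only M1 was compared with pLys, and its libraries held more ribosomal RNA. A stronger host response stays open as a hypothesis beside plasmid and RNA yield, which were not tested.

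With LacZ at 60 min 18 of 20 heat shock genes were called in DH10B and 1 in MG1655, where 9 were called over the list alone and 8 with a replicate block, and the list passed (camera FDR = 2.36e-07; adjusted p = 0.126 with an estimated correlation). At equal depth (a DH10B LacZ library's, a weak test) 18 of 20 list members were still called in DH10B. With lacZ and its counts left out, 2 members were called in MG1655. The count did not rest on 1 library, with at least 14 called in DH10B whichever of the 6 libraries was left out (14 to 16; at most 2 in MG1655). The strain difference itself was called for ibpA and, except without replicate 3, for dnaK, and a host difference in the response to LacZ is a hypothesis. Copy number, growth and inducer uptake of the strains were not tested.

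Several results stood out because a test of the difference between groups called genes. The construct effect differed between 60 and 15 min for 225 genes in DH10B, among them acid resistance genes such as gadA, and for 116 in MG1655, among them flagellar genes such as flgE. Construct effects differed between the strains for 43 genes with H3 (araE), 240 with Lux (araE), 317 with M1 (araE) and 52 with LacZ (gadC). Ribosomal RNA, left out of the tests, took more of the reads with M1 than with pLys: by 10.3 percentage points in DH10B at 15 min (90.2 ± 1.18% against 79.9 ± 0.954%), 7.21 at 60 min, and 6.19 and 6.41 in MG1655. The cause was not tested.

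For each count, other splits of its libraries were tested. A comparison of 3 with 3 libraries has 10 splits, too few to exclude chance: only the real split reached the real count. Real counts and the highest of the other splits were, for H3, Lux, M1 and LacZ: constructs in DH10B at 15 min 338 against 0, 120 against 3, 684 against 1, 8 against 1, at 60 min 91 against 27, 553 against 0, 1283 against 1, 477 against 2, in MG1655 at 15 min 225 against 0, 107 against 0, 573 against 1, 21 against 0, at 60 min 124 against 2, 130 against 0, 1311 against 0, 41 against 5. For pSB1C3, pLys and pD864 against no plasmid they were 12 against 2, 16 against 0, 17 against 0 at 15 min and 96 against 38, 204 against 52, 244 against 82 at 60 min. Chance is unlikely for counts with 50 splits. Of these, 1 reached the real count for the construct average (1192 against 662 in DH10B, 780 against 541 in MG1655). So did 1 for its time difference (225 against 59, 116 against 70) and time in empty plasmids (1031 against 465, 772 against 237). For strain differences 4, 2, 8 and 3 of 25 splits did so with H3, Lux, M1 and LacZ (43 against 68, 240 against 260, 317 against 1052, 52 against 305), so the count does not exclude chance. The other splits as large (3, 1, 7, 2) all left construct and plasmid libraries whole in 1 strain, which keeps or reverses the construct effect there, a structure of the samples and no measure of chance. The 17 splits mixed in both strains called at most 2 genes (with M1), and are too few for a share under 0.05.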

How the results depend on the processing

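Only the setting without the 3 shallow libraries was chosen after seeing the data. Counts of called genes stayed within 1.5 times the reported count in all 32 comparisons with RLE size factors, no low-count filter or all gene rows kept. They moved further, with the reported count in parentheses, with a replicate block in 9 of 32 (H3 DH10B 60 min 148 (91), pSB1C3 against no plasmid DH10B 60 min 145 (96), pLys against no plasmid DH10B 15 min 25 (16), H3 MG1655 15 min 371 (225), LacZ MG1655 15 min 33 (21), H3 MG1655 60 min 228 (124), LacZ MG1655 60 min 97 (41), strain difference H3 65 (43), strain difference LacZ 107 (52)), in a fit of only the groups compared in 8 (pSB1C3 against no plasmid DH10B 60 min 8 (96), pLys against no plasmid DH10B 15 min 28 (16), pLys against no plasmid DH10B 60 min 3 (204), pD864 against no plasmid DH10B 60 min 23 (244), Lux MG1655 15 min 162 (107), LacZ MG1655 15 min 12 (21), H3 MG1655 60 min 80 (124), LacZ MG1655 60 min 16 (41)), by DESeq2 in 4 (LacZ DH10B 15 min 5 (8), pSB1C3 against no plasmid DH10B 60 min 164 (96), pLys against no plasmid DH10B 15 min 27 (16), strain difference LacZ 90 (52)), and without the 3 shallow libraries in 5 of 21 (H3 DH10B 60 min 154 (91), pSB1C3 against no plasmid DH10B 60 min 36 (96), pLys against no plasmid DH10B 15 min 31 (16), pLys against no plasmid DH10B 60 min 74 (204), strain difference LacZ 81 (52)). In comparisons moved by the block, all 3 pairs correlated above 0.1 only with H3 and LacZ in MG1655 (for strain differences, not in DH10B). The cause of the shifts was not tested.

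With 1 library or replicate number left out, 53 of 162 counts moved by more than 1.5 times. The reported counts, with the lowest and highest of these, were, for H3, Lux, M1 and LacZ, 338 (183 to 308), 120 (85 to 118), 684 (515 to 637), 8 (7 to 9) in DH10B at 15 min, 91 (51 to 106), 553 (405 to 451), 1283 (1134 to 1203), 477 (280 to 441) at 60 min, 225 (118 to 184), 107 (66 to 99), 573 (429 to 507), 21 (12 to 24) in MG1655 at 15 min and 124 (61 to 112), 130 (76 to 99), 1311 (1128 to 1201), 41 (17 to 57) at 60 min. For pSB1C3, pLys and pD864 against no plasmid they were 12 (7 to 11), 16 (11 to 16), 17 (9 to 17) at 15 min and 96 (28 to 230), 204 (63 to 339), 244 (137 to 325) at 60 min. For DH10B and MG1655 they were 1192 (761 to 1093), 780 (430 to 654) in the average, 225 (62 to 240), 116 (35 to 92) in its time difference and 1031 (695 to 905), 772 (390 to 779) over time in empty plasmids, and for the strain differences of H3, Lux, M1 and LacZ 43 (12 to 57), 240 (48 to 181), 317 (141 to 285), 52 (6 to 91).

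Heat shock genes called higher with LacZ in MG1655 at 60 min numbered 1, and 8 with a replicate block, 3 by DESeq2, 0 in a fit of only the groups compared and 0 to 2 with 1 library left out. Among named genes, calls were lost in 284 of 2799 results with a library or replicate left out, 27 of 517 in a fit of only the groups compared, 18 of 326 without the shallow libraries, 12 of 543 with no low-count filter, 5 of 535 by DESeq2, 3 of 543 with RLE size factors, and 1 with all gene rows kept and 1 with a block. ydcD with pD864 against no plasmid at 60 min changed sign, to 0.50 without no-plasmid replicate 2 (the lowest of these values with a library left out was -4.31) and 0.49 without the 3 shallow libraries. Of 337 list results, 204 were lost with estimated correlation and 28 with fry. Depth limits genes with few reads, most in no-plasmid 60 min replicate 2.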
